A study of Homo sapiens with 9 samples.

How the data were processed

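Gene expression was measured in H157, an established human non-small cell lung cancer line, after 6 h with 1 of 9 compounds, each compared with cells given the solvent DMSO. Per the labels' protocols, cells were kept overnight in medium with little serum before treatment, total RNA was reverse transcribed, and the cDNA was coupled to the dyes Cy3 and Cy5. Each compound is 1 sample hybridised on 2 dye-swapped printed oligonucleotide arrays, 18 arrays in all. The labels give the DMSO control of all compounds 1 name and do not say whether it was 1 culture or 1 per compound.

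Each array file holds 36288 spots, of which 34776 carry gene probes and 1512 are control or blank spots. Per the deposited column guide, the spot intensity of each channel is a trimmed pixel mean from which the authors' image software had already subtracted the local background. The guide also describes a quality fraction from 0 (bad) to 1 (good) that the authors deposited for each spot. The deposited calibrated ratio equals the ratio of both intensities divided by 1 constant per array. The authors' deposited summary table holds log2 values that equal the log2 of the mean calibrated ratio of the 2 arrays within 0.001 for 100% of values. Its scale was settled by that comparison, its direction, like that of the arrays, is likely only, it is not centred, and its medians lay between 0.0306 (wortmannin) and 0.0648 (DZ-50). The image analysis program and any genome build are not given in the sources used here, so no coordinates are printed.

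The median red-column signal lay between 128.1 and 845.5 and the median green-column signal between 128.2 and 455.4 intensity units. Both channels exceeded local background by 2 background SDs at 95.6% to 99.9% of probes. In the brighter channel, however, 7.0% to 12.7% of probes exceeded the 95th percentile of the 188 negative control probes. The number of arrays limits the precision of every value. Spots with a quality of 0 were left out, which removed 0.242% to 0.673% of spots on arrays labelled with treated RNA in Cy5 and 1.99% to 4.21% on arrays labelled with treated RNA in Cy3. Because the deposited signals were already corrected, no further background correction was applied in the main setting. Signals were floored at 1 before taking logs. Log2 ratios were normalised within each array by global loess (span 0.3, 4 iterations, control spots at weight 0) in limma 3.58.1 under R 4.3.3. Tables and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

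The direction of the ratios is likely, not certain. The design fixed before the data were examined turned the sign of arrays with treated RNA in Cy3, but the files were read as holding treated over DMSO in the same columns on both arrays, and no sign was turned. The basis is that the labels list the treated RNA as channel 1, that the background levels of the columns change places between the orientations, and that the authors' own summary averages both ratios without turning either. After removal of the mean over compounds, both arrays of a compound correlated positively across genes for 9 of 9 compounds (r from 0.047 with miltefosine to 0.55 with perifosine, mean r 0.315, against -0.039 for arrays of different compounds). Before that removal r ran from -0.416 to 0.224 and was negative with LY294002 (-0.276), wortmannin (-0.416), OSU-03012 (-0.154) and DZ-50 (-0.039). Paired arrays of opposite direction would give negative r after the removal. The positive r in 9 of 9 compounds thus argues against turning 1 orientation, least with miltefosine. It cannot tell treated over DMSO from the reverse on both arrays. Genes are not independent replicates in these correlations. With the signs turned as the design had it, limma called 16130 features over all compounds, 9491 over the PI3K and mTOR inhibitors, 14241 over the other compounds and 0 for the difference of the sets. The part of the profile common to all compounds correlated negatively between the orientations (r = -0.26), so dye effects remained in each orientation and cancel only as far as averaging removes them. Arrays of different compounds within 1 orientation correlated at 0.22 or more.

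A table of platform annotation named 21592 probes with 1 gene, of which 21493 were brought to current symbols through their gene identifiers, and a RefSeq accession in the array files named a further 2394. Another 1014 probes list several genes and 9776 have no gene name here; both kinds were kept as unnamed features. The gene table used for symbols belongs to assembly GRCh38.p14 and served for names only. Where a gene had several probes, the one with the highest mean intensity was used. AKT1, AKT2, PKIB, BRD8 and, with OSU-03012, CCN1 have another probe of opposite sign in a comparison below where they are named. The 2 arrays of a compound were averaged, and a feature was tested if measured on both arrays of all 9 compounds, which left 25081 features with 15184 named genes.

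The compounds served as replicates in 4 tests with limma (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05): all 9 compounds against 0, the 3 inhibitors of PI3K or mTOR against 0, the other 6 against 0, and the difference of these sets. Errors are limma's standard errors (SE). In the tests of the sets and of their difference, all 9 compounds share 1 spread around their set means. Errors over the 3 inhibitors thus also rest on the other 6 compounds, and the reverse. If 1 DMSO sample lies under every ratio, its own spread is left out of the errors; if each compound had its own, that spread is part of them. In either case p-values measure only the spread between compounds' ratios. Shared-control simulations assume 1 DMSO sample. Single compounds have no replicate check, and features were counted there if changed at least 2-fold in the same direction on both arrays. The rule for naming genes took, in each tested comparison, up to 12 called genes per direction with the largest change and the same sign in every compound of the set (for the difference, sets without overlap), or the 5 with the smallest p where none passed. For single compounds it took the 5 highest and 5 lowest genes past 2-fold on both arrays, for compound pairs the 5 highest and lowest differences, from the gene lists the members with the largest values, and the list built from the title in full. Some genes that the rule took are not reported here.

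Before the data were examined, 22 gene lists were fixed: genes of the study's title with close relatives, sterol synthesis, fatty acid synthesis, ATF4 stress response, endoplasmic reticulum chaperones, heat shock, oxidative and metal response, FOXO targets, immediate early genes, NF-kappaB targets, interferon response, G1/S, G2/M, growth arrest and p53, glycolysis and hypoxia, ribosomal proteins, ribosome biogenesis, lysosome and autophagy, TGF-beta and adhesion, and markers of fibroblasts, leukocytes and endothelial cells. They were tested with camera (preset correlation 0.01) and adjusted over 88 tests, with camera using an estimated correlation and fry beside it. For single compounds, list medians were ranked among 10000 random lists matched on mean intensity in 10 bins.

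The tests were checked on simulated data over 25081 genes before use. For log2 changes of 0.5, 50 of 50 changed genes were recovered over all compounds, 43 of 50 over the PI3K and mTOR inhibitors, 49 of 50 over the other compounds and 40 of 50 for the difference. Unchanged genes made up 6.5%, 6.3%, 4.8% and 3.6% of the calls in these comparisons. The simulated errors were independent between compounds, with no shared DMSO sample and no dye effect. These shares therefore do not give the share of false calls in the real tests against 0, where both may be present.

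Alternatives covered background correction, normalisation within and between arrays, filters on dim probes, the rule for several probes, each dye orientation alone, the authors' summary values, limma with trend and robust settings, the 18 arrays with compound as a random block, and each compound left out in turn. After the data had been seen, 4 more were added: normexp with an offset of 50 on a rebuilt foreground, loess within each printing pen, a filter on the negative control probes, and calls made in the same direction in each orientation alone.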

Results

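The data comprise 18 two-colour arrays of H157 cells, covering 9 compounds given for 6 h. LY294002 (10 µM) and wortmannin (100 nM) inhibit PI3K, and rapamycin (100 nM) inhibits mTOR. The other 6 compounds, OSU-03012, PIA23, perifosine, miltefosine, API-2 and DZ-50, were given at 10 µM. The title of the study names RHOB, a small GTPase described there as a tumour suppressor, together with PACT, PKR, C/EBPbeta and Akt. On each array, 7.0% to 12.7% of probes were brighter than the 95th percentile of the 188 negative control probes. Values are log2 ratios of treated over DMSO, with the direction likely rather than certain, on the basis given with the processing. If the Cy3 arrays ran the other way, each value would be the mean of its Cy5 reading and its Cy3 reading with the sign changed.

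RHOB stood at 2.52 with PIA23, 1.92 with perifosine and 1.07 with miltefosine, and between 0.01 and 0.37 with the remaining compounds. On the paired arrays RHOB read 1.41 and 3.62 with PIA23, 0.99 and 2.85 with perifosine, and 0.06 and 2.08 with miltefosine, always higher where the treated RNA was labelled with Cy3. Over the other 6 compounds RHOB rose by 1.03 (SE 0.27, n = 6, adjusted p = 0.0173), with 0.38 and 1.68 in the Cy5 and Cy3 orientations, and over all 9 by 0.73 (SE 0.25, adjusted p = 0.0455). The RHOB call over all 9 compounds ended without PIA23 (0.50, adjusted p = 0.0691), without perifosine (0.57, adjusted p = 0.0964), without miltefosine (0.68, adjusted p = 0.0901), without OSU-03012 (0.78, adjusted p = 0.0591) or without API-2 (0.77, adjusted p = 0.0586). It also ended with no background correction (0.34), with normexp (0.59), with loess within each pen (0.66), in the Cy5 orientation alone (0.22) and with limma trend and robust settings (adjusted p = 0.0638). Over the other 6 compounds the RHOB call held without each single compound, and ended with no background correction (0.50, adjusted p = 0.0639) and in the Cy5 orientation alone (adjusted p = 0.111). RHOA, a related GTPase, rose over the other 6 compounds by 0.43 (SE 0.13, adjusted p = 0.032) and read 0.99 with PIA23 and 1.01 with perifosine. The RHOA call ended without PIA23 (0.32, adjusted p = 0.0902), without perifosine (0.32, adjusted p = 0.0884) or without miltefosine (0.42, adjusted p = 0.0744), with no background correction, with loess within each pen and in the Cy5 orientation alone (0.21). CEBPB, which encodes C/EBPbeta, read 0.16 (SE 0.10, adjusted p = 0.235) over the other 6 compounds and was not called.

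Of the 13 measured genes in the list built from the title, 4 rose, 2 fell and 7 were not called over the other 6 compounds, with 4 higher and 3 lower when adjusted over the list alone. CEBPG rose by 0.52 (SE 0.06, adjusted p = 0.00106), while EIF2S1, the translation initiation factor phosphorylated by PKR, fell by 0.23 (SE 0.07, adjusted p = 0.0244). The EIF2S1 call ended without PIA23 (adjusted p = 0.0681), without miltefosine (adjusted p = 0.0587) or without API-2 (adjusted p = 0.0715), at values of -0.21, -0.23 and -0.20, and with loess within each pen it read -0.014. PRKRA, which encodes PACT, read -0.16 (SE 0.08, adjusted p = 0.141) and EIF2AK2, which encodes PKR, read -0.19 (SE 0.07, adjusted p = 0.0705). PRKRA read 0.011 with loess within each pen and was called lower with median centring (-0.23), with the authors' values (-0.21) and in the Cy5 orientation alone (-0.30). EIF2AK2 was called lower with the same 3 settings, with the random block and without OSU-03012 (-0.26, adjusted p = 0.0182). AKT1 fell by 0.21 (SE 0.05, adjusted p = 0.0128), while AKT2 read 0.026 (adjusted p = 0.695) with -0.15 and 0.20 by orientation. AKT1 read 0.025 with loess within each pen and -0.078 with the mean of its probes, neither called. RHOC (0.063, adjusted p = 0.506), CEBPA (0.18, adjusted p = 0.214) and CEBPD (-0.003, adjusted p = 0.976) were not called, CEBPD with -0.37 and 0.37 by orientation. CEBPA was called higher without DZ-50 (0.28, adjusted p = 0.0463). The list as a whole was not called in any tested comparison, with adjusted p = 0.513 over the other 6 compounds.

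Across all 9 compounds, PCNA, the sliding clamp of DNA replication, fell by 0.91 (SE 0.075, n = 9, lower in 9 of 9, adjusted p = 0.00011), with -0.88 on arrays with treated RNA in Cy5 and -0.94 on those in Cy3. The naming rule required the same sign in every compound of a set, so such counts add no support, here and below. A deviation in a DMSO sample shared by all compounds would shift every ratio alike. The p-values against 0 do not cover it. OSGIN1, an oxidative stress gene, fell by 0.80 (SE 0.075, adjusted p = 0.000195), and the co-chaperone DNAJA1 fell by 0.64 (SE 0.11, adjusted p = 0.00238). SOD2, the mitochondrial superoxide dismutase, rose by 0.87 (SE 0.16, adjusted p = 0.00372), and the amino acid transporter SLC38A2 rose by 0.69 (SE 0.11, adjusted p = 0.00211). CXCL8, the chemokine interleukin-8, rose by 2.22 (SE 0.72, adjusted p = 0.0361). That CXCL8 call ended without PIA23 (1.78, adjusted p = 0.0754), without perifosine (1.70, adjusted p = 0.0712) or without miltefosine (1.85, adjusted p = 0.0834), with no background correction, with loess within each pen and with limma trend and robust settings. Further named genes that rose were GEM, CCL20, SAT1, CD55, TSC22D1, USP53, PPP1R15A and IRAK2, and those that fell were HSPA4L, UGT1A9, POLE2, DYNLL1P3, TMPO, MAGEF1, HSP90AA2P and SKP2. Without perifosine or without miltefosine the calls of GEM (0.98 and 1.11), CCL20 (0.70 and 0.70) and CD55 (0.59 and 0.65) ended, at adjusted p from 0.0546 to 0.0709, as did those of CCL20 (0.84) and CD55 (0.66) without PIA23. TGM4 met the naming rule at -0.78 (adjusted p = 0.00104), but read -3.65 in the Cy5 orientation and 2.09 in the Cy3 orientation.

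Among the 22 measured genes of G1/S and DNA replication, 11 fell, 0 rose and 11 were not called over all 9 compounds, and 11 fell when adjusted over the list alone. MCM3, part of the replicative helicase, fell by 0.48 (SE 0.11, adjusted p = 0.00779) and CCND3, which encodes cyclin D3, by 0.42 (SE 0.07, adjusted p = 0.00201). The list median was -0.13, with -0.17 and -0.25 in the Cy5 and Cy3 orientations, and camera gave adjusted p = 5.4e-05, against adjusted p = 0.395 with an estimated correlation. Heat shock genes followed, with 8 of 14 lower, 0 higher and 6 not called, and 1 higher and 11 lower when adjusted over the list alone. HSP90AA1 fell by 0.47 (SE 0.11, adjusted p = 0.0102) and HSPH1 by 0.44 (SE 0.10, adjusted p = 0.00738), the heat shock median was -0.31 (-0.28 and -0.39 by orientation), and camera gave adjusted p = 0.000269, against adjusted p = 0.395 with an estimated correlation. Oxidative and metal response genes were shifted down (7 of 16 lower, 2 higher; adjusted p = 0.0414, and adjusted p = 0.395 with an estimated correlation). FOXO targets were shifted up (6 of 21 higher, 2 lower; adjusted p = 0.0414, and adjusted p = 0.395 with an estimated correlation). KLF6, a transcription factor, rose by 0.64 (SE 0.21, adjusted p = 0.0359), a call that ended without PIA23 (0.50, adjusted p = 0.0728), perifosine (0.50, adjusted p = 0.0723), miltefosine (0.55, adjusted p = 0.0825) or OSU-03012 (0.68, adjusted p = 0.0511), with no background correction and with loess within each pen.

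In total 7481 of 25081 features were called over all 9 compounds, 3575 higher and 3906 lower, and 52 of them changed by at least 1.5-fold. In each dye orientation alone, where dye effects do not cancel, 1479 features were called in the same direction and 5786 in opposite directions, where independent lists would give 3481 of each. Of the 7481 calls, 5021 had the same sign in both orientations and 2460 (32.9%) had opposite signs. Of the 52 larger changes, 51 had the same sign in both orientations. Loess within each printing pen called 2831 features, the filter on negative control probes, which of the named genes kept HSP90AA2P and HSP90AA1 here, called 746, and the authors' summary values gave 6789 higher and 3229 lower.

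With the PI3K and mTOR inhibitors, PSAT1, an enzyme of serine synthesis, fell by 1.43 (SE 0.19, n = 3, lower in 3 of 3, adjusted p = 0.0158), with -1.99 for LY294002, -1.24 for wortmannin and -1.05 for rapamycin. SLC7A5, the light chain of the large neutral amino acid transporter, fell by 0.97 (SE 0.13, adjusted p = 0.0158). The glycolytic enzymes PGAM1 and LDHA fell by 0.82 (SE 0.09, adjusted p = 0.013) and by 0.74 (SE 0.10, adjusted p = 0.0158), and PDK1, the pyruvate dehydrogenase kinase, fell by 0.73 (SE 0.09, adjusted p = 0.013). HBP1, a transcriptional repressor, rose by 0.69 (SE 0.11, adjusted p = 0.0207), with 0.22 in the Cy5 orientation and 1.17 in the Cy3 orientation. Without LY294002 or without wortmannin none of these genes was called, with PSAT1 at -1.14 (adjusted p = 0.12) and -1.52 (adjusted p = 0.157) and HBP1 at 0.63 (adjusted p = 0.197) and 0.65 (adjusted p = 0.204). HBP1 was not called without rapamycin either (0.80, adjusted p = 0.061), and of these genes SLC7A5 alone kept its call with limma trend and robust settings.

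Other named genes that fell with these inhibitors were OSGIN1, DDIT4, PCNA, CCND2, PKIB, RTF1 and DAO. KLRC4, BRD8, CREBRF, FNDC3A, CRBN and RICTOR rose, and RICTOR, a subunit of mTOR complex 2, read 0.45 (SE 0.09, adjusted p = 0.0496). The RICTOR call ended without LY294002 (0.42, adjusted p = 0.284), wortmannin (0.43, adjusted p = 0.289) or rapamycin (0.49, adjusted p = 0.141), and, with its value unmoved, without PIA23, perifosine, miltefosine or DZ-50 (adjusted p = 0.0504, 0.0611, 0.073 and 0.0583). In the Cy5 orientation alone RICTOR read 0.018. None of these falling or rising genes was called without LY294002, wortmannin or rapamycin, at adjusted p from 0.12 to 0.294, from 0.157 to 0.289 and from 0.0549 to 0.167. With their values unmoved, calls also ended without perifosine (DDIT4, adjusted p = 0.0522, and CCND2, adjusted p = 0.063), without miltefosine (DDIT4, CCND2, FNDC3A and CRBN, adjusted p = 0.0636, 0.0525, 0.0548 and 0.0525) and without DZ-50 (CCND2, adjusted p = 0.0589, and RTF1, adjusted p = 0.0581). BRD8 (0.21 and 1.10), CRBN (0.03 and 0.87) and RTF1 (-0.098 and -1.14) differed between the Cy5 and Cy3 orientations. With the mean of their probes, BRD8 read 0.35 and PKIB -0.25, neither called. OOSP2, CFAP107, EDDM3B and RB1CC1 were also called higher but had opposite signs in the orientations. OOSP2, CFAP107, EDDM3B and FNDC3A had a channel near background on at least 1 array.

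In the ATF4 stress list, 3 of 26 measured genes fell with the PI3K and mTOR inhibitors, 0 rose and 23 were not called, while 14 fell when adjusted over the list alone. The list median was -0.29, with -0.22 and -0.36 by orientation, and camera gave adjusted p = 1.4e-10, against adjusted p = 0.386 with an estimated correlation. None of the 23 sterol synthesis genes was called over all features and 8 were lower when adjusted over the list alone. HMGCS1, an early enzyme of the pathway, read -0.93 (SE 0.35, adjusted p = 0.217) and FDPS read -0.69 (SE 0.15, adjusted p = 0.0598). FDPS was called lower in each orientation alone, with scale normalisation, with the authors' values, with the random block and without API-2 (adjusted p = 0.0433), and HMGCS1 in the Cy5 orientation alone (-1.29). The sterol median was -0.34 (-0.28 and -0.35 by orientation; adjusted p = 7.29e-07, and adjusted p = 0.395 with an estimated correlation). Glycolysis and hypoxia genes were shifted down (3 of 21 lower, 0 higher; adjusted p = 2.57e-05), as were ribosome biogenesis genes (1 of 19 lower; adjusted p = 0.000117), G1/S genes (1 of 22 lower; adjusted p = 0.000117) and heat shock genes (1 of 14 lower; adjusted p = 1.75e-07), each with adjusted p = 0.395 with an estimated correlation. Downward shifts were also called for endoplasmic reticulum chaperones (adjusted p = 0.00404, and adjusted p = 0.416 with an estimated correlation), fatty acid synthesis (adjusted p = 0.0212, and adjusted p = 0.552 with an estimated correlation) and oxidative and metal response (adjusted p = 0.000861, and adjusted p = 0.386 with an estimated correlation). FOXO targets were shifted up (1 of 21 higher, RICTOR; adjusted p = 0.0451, and adjusted p = 0.479 with an estimated correlation).

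Over these 3 inhibitors, limma called 150 features, 34 higher and 116 lower. Fewer calls were made with any inhibitor left out, with 2 left without LY294002, 0 without wortmannin and 17 without rapamycin. With all 3, 4325 features passed an unadjusted p of 0.05. Such fits rest on fewer compounds, so a lost call need not mean a smaller change. PSAT1, for example, shrank without LY294002 but not without wortmannin. Limma with trend and robust settings called 6, loess within each pen 2 higher and 15 lower, median centring 111 higher and 172 lower, and the authors' values 554 higher and 243 lower. Mean values in the orientations correlated at r = -0.33 across genes, and 130 of the 150 calls had the same sign in both. In each orientation alone 109 features were called in the same direction and 866 in opposite directions, where independent lists would give 319.3 and 320.5.

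Over the other 6 compounds, CXCL8 rose by 3.18 (SE 0.75, n = 6, higher in 6 of 6, adjusted p = 0.0107), with 2.71 and 3.66 in the Cy5 and Cy3 orientations. That mean rests mostly on PIA23 (5.67), perifosine (6.33) and miltefosine (5.12), and the values with OSU-03012, API-2 and DZ-50 lay below it. The same 3 compounds read 4.02, 3.42 and 2.55 for CXCL3 and 3.74, 3.03 and 1.94 for GEM. CXCL3 rose by 2.09 (SE 0.40, adjusted p = 0.00469), CXCL2 by 2.05 (SE 0.28, adjusted p = 0.00165) and IL1A, which encodes interleukin-1 alpha, by 1.31 (SE 0.23, adjusted p = 0.00368). GEM, a small GTP-binding protein, rose by 1.73 (SE 0.38, adjusted p = 0.00832), and GPRC5A by 1.27 (SE 0.27, adjusted p = 0.00648). With limma trend and robust settings the calls of CXCL8 (adjusted p = 0.696), CXCL3 (adjusted p = 0.125), CXCL2 (adjusted p = 0.0703) and GEM (adjusted p = 0.0653) ended. The genes that fell included PCNA at -0.96 (SE 0.09, adjusted p = 0.000462), the condensin subunit SMC4 at -0.77 (SE 0.11, adjusted p = 0.00188) and ANLN, needed for cytokinesis, at -0.68 (SE 0.08, adjusted p = 0.00109).

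CXCL5, CCL20, CLDN1, a tight junction gene, SAT1, CD55 and GPAT3 completed the named genes that rose, and HSPA4L, OSGIN1, TMPO, POLE2, DLGAP5, UGT1A9, ZNF680 and ZNF726P1 those that fell. The CCL20 call ended without miltefosine (0.94, adjusted p = 0.0521). TGM4 was called lower at -0.85 (SE 0.13, adjusted p = 0.00209), but read -3.93 in the Cy5 orientation and 2.23 in the Cy3 orientation.

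Of 20 measured NF-kappaB targets, 14 rose, 0 fell and 6 were not called over the other 6 compounds, with 14 higher and 1 lower when adjusted over the list alone, and 12 of the 14 were called higher in both orientations. CXCL8, CXCL3, CXCL2 and IL1A were the members with the largest values. The list median was 0.68 (0.43 and 0.95 by orientation), and camera gave adjusted p = 1.6e-06, against adjusted p = 0.395 with an estimated correlation. In the ATF4 stress list, 12 of 26 rose, 0 fell and 14 were not called, with 13 higher when adjusted over the list alone. PPP1R15A, a phosphatase subunit acting on eIF2alpha, rose by 0.90 (SE 0.12, adjusted p = 0.0014) and TRIB3 by 0.81 (SE 0.10, adjusted p = 0.0011). The ATF4 median was 0.23 (0.16 and 0.37 by orientation; adjusted p = 2.01e-05, and adjusted p = 0.395 with an estimated correlation).

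Lysosome and autophagy genes were shifted up (12 of 22 higher, 1 lower; 12 and 1 adjusted over the list alone), with MAP1LC3B at 0.71 (SE 0.18, adjusted p = 0.0144) and SQSTM1 at 0.58 (SE 0.12, adjusted p = 0.0065), the latter at 0.088 in the Cy5 orientation alone. Camera gave adjusted p = 0.000396 for them, against adjusted p = 0.395 with an estimated correlation. Immediate early genes were shifted up (10 of 23 higher, 1 lower; adjusted p = 0.000861, and adjusted p = 0.509 with an estimated correlation), with KLF2 at 1.23 (SE 0.31, adjusted p = 0.0152) and DUSP5, a phosphatase of MAP kinases, at 0.98 (SE 0.22, adjusted p = 0.00902), while the list median was -0.006 with OSU-03012 and -0.057 with DZ-50. Endoplasmic reticulum chaperone genes were shifted up (8 of 16 higher; adjusted p = 0.0202, and adjusted p = 0.509 with an estimated correlation), led by XBP1 at 0.76 (SE 0.09, adjusted p = 0.00117). Downward shifts were called for G2/M genes (8 of 21 lower, 1 higher; adjusted p = 0.00981, and adjusted p = 0.584 with an estimated correlation), G1/S genes (10 of 22 lower; adjusted p = 0.000283, and adjusted p = 0.395 with an estimated correlation) and heat shock genes (6 of 14 lower; adjusted p = 0.00981, and adjusted p = 0.509 with an estimated correlation). By compound the G2/M median was -0.47 with PIA23, -0.46 with perifosine and -0.45 with miltefosine, against 0.032 with OSU-03012, -0.002 with API-2 and -0.06 with DZ-50, and the G1/S median was 0.027 with API-2. HMMR, the hyaluronan-mediated motility receptor, fell by 0.61 (SE 0.12, adjusted p = 0.00544).

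Over the other 6 compounds 7165 features were called, 3452 higher and 3713 lower. Of these calls, 5363 had the same sign in both orientations and 1802 (25.2%) had opposite signs. At least 1.5-fold changes were seen in 268, of which 266 had the same sign in both orientations. In each orientation alone 1591 were called in the same direction and 3987 in opposite directions, where independent lists would give 2692 and 2691; loess within each pen called 3477, the negative control filter 994, and the authors' values gave 6466 higher and 3140 lower.

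The difference between the sets was tested directly. SLC7A5 was higher with the other 6 compounds than with the PI3K and mTOR inhibitors by 1.55 (SE 0.16, n = 6 and 3, adjusted p = 0.00762), with means of 0.58 and -0.97. Its heavy chain SLC3A2 differed by 0.93 (SE 0.11, adjusted p = 0.0126), the glutamine transporter SLC1A5 by 0.74 (SE 0.10, adjusted p = 0.0356) and the transcription factor CEBPG by 0.86 (SE 0.10, adjusted p = 0.014). XBP1 and HERPUD1, of the unfolded protein response, differed by 1.16 (SE 0.16, adjusted p = 0.0413) and 1.07 (SE 0.16, adjusted p = 0.0416). SARS1, the seryl-tRNA synthetase, differed by 1.06 (SE 0.15, adjusted p = 0.0416), and SLC16A1, ARF4 and PRNP were also higher. Without LY294002 or without wortmannin none of these was called, with SLC7A5 at 1.39 (adjusted p = 0.0743) and 1.57 (adjusted p = 0.109). With no background correction SLC7A5 read 0.99 (adjusted p = 0.128) and CEBPG 0.36 (adjusted p = 0.203). Without rapamycin the calls of SLC3A2 (0.96, adjusted p = 0.0757), CEBPG (0.85, adjusted p = 0.0945), XBP1 (1.24, adjusted p = 0.103), HERPUD1 (1.10, adjusted p = 0.143) and SARS1 (1.10, adjusted p = 0.134) ended. Without miltefosine those of CEBPG (adjusted p = 0.0578), XBP1 (adjusted p = 0.102), SLC1A5, HERPUD1 and SARS1 (adjusted p = 0.0975 each) ended. XBP1, HERPUD1, SARS1 and SLC1A5 also lost their call without perifosine (adjusted p = 0.0887, 0.0778, 0.0887 and 0.0786), XBP1, SARS1 and SLC1A5 without OSU-03012 (adjusted p = 0.0671, 0.0629 and 0.0629), HERPUD1 and SARS1 without PIA23 (adjusted p = 0.0753 each), and HERPUD1 without API-2 (adjusted p = 0.0532). SLC16A1, ARF4 and PRNP lost theirs without rapamycin, OSU-03012, PIA23, perifosine or miltefosine, at adjusted p from 0.0503 to 0.12, and SLC16A1 without API-2 (0.72, adjusted p = 0.0532).

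**Figure D1:**
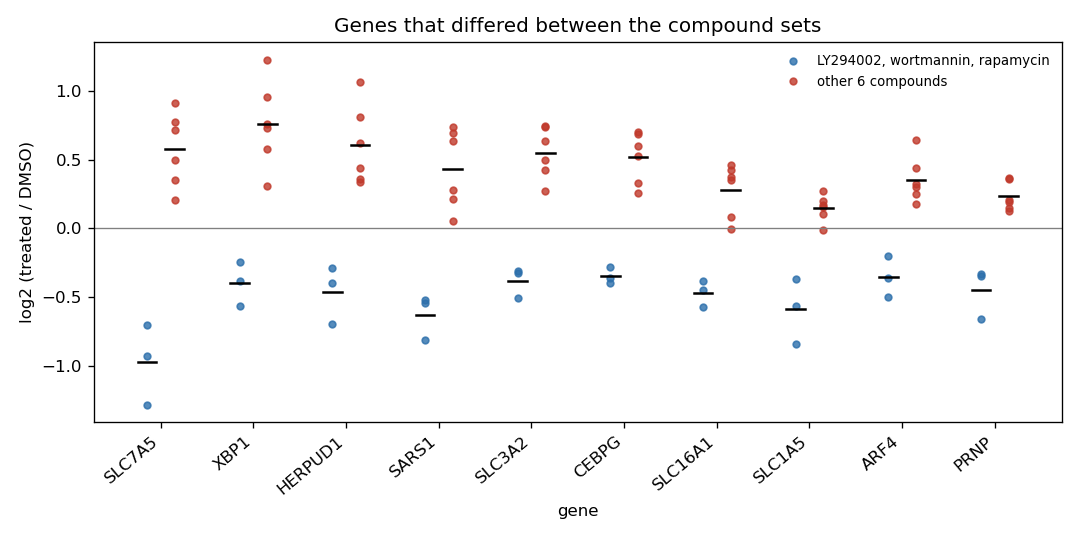
Log2 ratio of treated over DMSO (y axis) for the 10 named genes that differed between the compound sets (x axis), 1 point per compound and a black bar at each set's mean. All 3 values with LY294002, wortmannin and rapamycin lie below all 6 values with the other compounds for each gene, as the rule for naming these genes required. The set means for SLC7A5, for example, are -0.97 and 0.58.

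Limma called 14 features for this difference, 14 higher and 0 lower with the other 6 compounds, 10 of them named, and 2768 passed an unadjusted p of 0.05. All 14 had the same sign in both orientations, and the orientations correlated at r = 0.584 across genes for this difference. The genes with the smallest p on the lower side were not called, among them H1-3 at -0.70 (SE 0.12, adjusted p = 0.0844) and KLRC4 at -0.65 (SE 0.11, adjusted p = 0.0787), then BRD8 at -0.61, LRRC23 at -0.43 and RIBC1 at -0.36. Leaving out LY294002 or wortmannin left 0 calls, leaving out 1 of the remaining compounds left 4 to 24, and the 18 arrays with compound as a random block gave 64 higher and 7 lower.

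Within the ATF4 stress list, 4 of 26 genes were higher in the difference and 17 when adjusted over the list alone, with a median of 0.61 (0.37 and 0.85 by orientation) and camera adjusted p = 3.53e-26, against adjusted p = 0.13 with an estimated correlation. Sterol synthesis genes were shifted up in the difference (0 of 23 called, 12 adjusted over the list alone; adjusted p = 5.03e-10, and adjusted p = 0.395 with an estimated correlation). The same direction was called for NF-kappaB targets (adjusted p = 1.6e-06), glycolysis and hypoxia (adjusted p = 0.000117), ribosome biogenesis (adjusted p = 3.1e-05) and lysosome and autophagy (adjusted p = 0.014), each with adjusted p = 0.395 with an estimated correlation. Endoplasmic reticulum chaperones were also shifted up (2 of 16 higher; adjusted p = 1.69e-07, and adjusted p = 0.386 with an estimated correlation). Heat shock (adjusted p = 0.00981), immediate early (adjusted p = 0.00039) and fatty acid synthesis genes (adjusted p = 0.00462) were shifted up as well, each with adjusted p = 0.509 with an estimated correlation. G2/M genes (adjusted p = 0.00155, and adjusted p = 0.509 with an estimated correlation) and interferon response genes (adjusted p = 0.00866, and adjusted p = 0.395 with an estimated correlation) were shifted down. By compound, the list medians of the sets did not overlap for ATF4 stress, endoplasmic reticulum chaperones, NF-kappaB targets and ribosome biogenesis. They overlapped for the other lists called in the difference, among them sterol synthesis, with API-2 at -0.18, rapamycin at -0.14 and OSU-03012 at 0.46.

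Camera called 37 of 88 list tests in all, and 0 with an estimated correlation, where the lowest adjusted p was 0.13; fry, which asks whether a list moves on balance one way, called 18. NF-kappaB targets, immediate early genes and lysosome and autophagy genes were also shifted up over all 9 compounds (adjusted p = 0.000159, 0.00981 and 0.00155, and adjusted p = 0.494, 0.605 and 0.395 with an estimated correlation). Ribosomal proteins, growth arrest and p53 genes, TGF-beta and adhesion genes, and the markers of fibroblasts, leukocytes and endothelial cells were not called by camera in any comparison, with adjusted p of 0.367, 0.603, 0.0717, 0.823, 0.547 and 0.679 over all 9 compounds. Of these, fry called TGF-beta and adhesion genes over all 9 compounds (adjusted p = 0.0421). Median, mean and test differed in sign for glycolysis and fibroblast lists over the other 6 compounds, G2/M over the PI3K and mTOR inhibitors, and FOXO and endothelial lists in the difference, none of which was called.

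**Figure D2:**
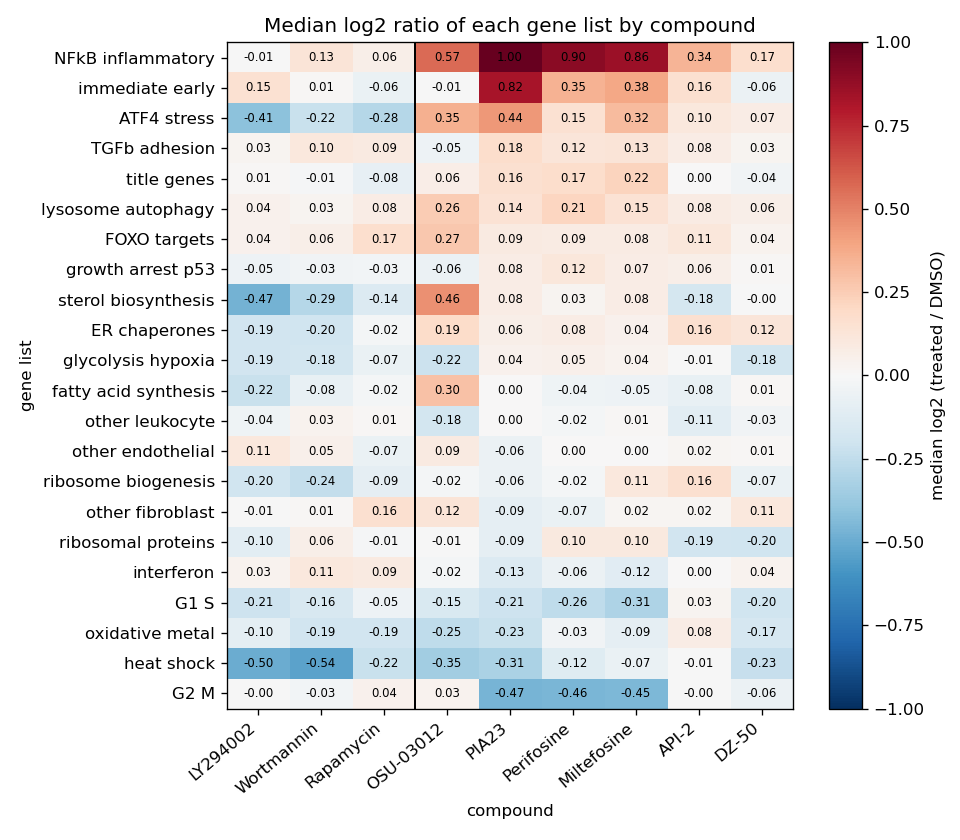
Median log2 ratio of treated over DMSO for each of the 22 gene lists (y axis) by compound (x axis, the PI3K and mTOR inhibitors left of the line), with colour and printed number giving the median. NF-kappaB targets read 0.90 with perifosine and 0.86 with miltefosine, and ATF4 stress genes read -0.41 with LY294002.

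Features changed at least 2-fold on both arrays were counted for single compounds, in the ratio direction taken as likely. PIA23 gave 62 higher and 195 lower, perifosine 58 and 12, miltefosine 16 and 2, and API-2 6 and 34. OSU-03012 gave 4 and 3, LY294002 1 and 6, wortmannin 1 and 4, rapamycin 0 and 1, and DZ-50 0 and 0. These are counts from 1 sample each. With the Cy3 arrays turned, the totals would be 1 for PIA23, 2 for perifosine, 4 for miltefosine, 2 for API-2, 8 for OSU-03012 and 1 for each of LY294002, wortmannin, rapamycin and DZ-50. In the direction taken, CXCL8 stood at 6.33 with perifosine, 5.67 with PIA23 and 5.12 with miltefosine, and TM4SF1, a membrane protein, at 3.24, 3.14 and 3.10. With the Cy3 arrays turned CXCL8 would read -0.54, -0.54 and -0.85, and TM4SF1 -0.072, 0.015 and -0.76. The positive r between paired arrays, given with the processing, argues against that reading. With LY294002, HMGCS1 stood at -1.68 and TXNIP at 1.51; with wortmannin SOD2 stood at 1.79 and PSAT1 at -1.24. OSU-03012 had CXCL2 at 1.73 and CCN1 at -1.33 (-1.85 and 0.069 on its other probes), and API-2 had GPAT3 at 1.38 and ZNF117 at -1.88, where ZNF117 was close to background on 7 arrays. Turned, the values named here for LY294002, wortmannin, OSU-03012 and API-2 would lie, on the probes used, between -0.40 (SOD2) and 0.55 (ZNF117). Of the lower features, 174 of 195 with PIA23 and 32 of 34 with API-2 have no gene name here.

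**Figure D3:**
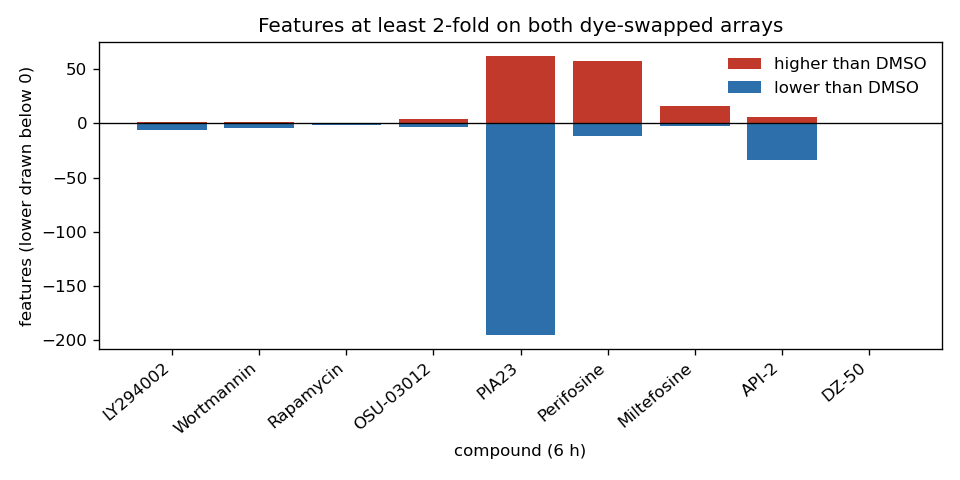
Number of features at least 2-fold higher (bars above 0) or lower (bars below 0) than DMSO on both dye-swapped arrays (y axis) for each compound after 6 h (x axis). PIA23 has 62 higher and 195 lower features and DZ-50 has 0 of either.

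Perifosine and miltefosine, both alkylphosphocholines, were compared at 10 µM and 6 h. No feature differed at least 2-fold in both orientations, the profiles correlated at r = 0.728 across genes (0.22 and -0.057 between opposite dye orientations), and 16 higher and 1 lower features were 2-fold with both, where independent lists would share 0.0364 and 0.000877. Unchanged samples simulated against 1 shared control shared 0.333 higher and 0.0833 lower features on average over 36 pairs, at most 2 and 1, and part of the observed overlap may come from a shared DMSO sample. Perifosine minus miltefosine read 1.21 for CXCL8 (95% interval 0.67 to 1.75, adjusted p = 0.337), 0.76 for CXCL2 (0.27 to 1.25) and 0.14 for TM4SF1 (-0.48 to 0.75). These unadjusted intervals cover the spread between arrays only, and with 1 sample each they cannot show a difference between the compounds. Limma over the 18 arrays called 0 differences, with 1263 features at an unadjusted p under 0.05. SYCP3, POLE2, GEM and GPRC5A gave the other large positive differences (1.29, 1.28, 1.09 and 0.93), and THOC3, CHRM5, ZNF615 and PPP1R17 were among the most negative (-1.15, -1.05, -1.02 and -0.97). LY294002 and wortmannin, whose doses differed, correlated at r = 0.614 across genes, with SOD2 at 0.45 and 1.79. Between opposite dye orientations they correlated at -0.327 and -0.41, and at 0.263 after removal of the mean over compounds.

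Profiles of the 36 compound pairs correlated across genes at a median r of 0.346, from 0.072 for LY294002 with perifosine to 0.772 for PIA23 with perifosine (between opposite dye orientations -0.417 and -0.279, and 0.163 and 0.187). Unchanged samples simulated against 1 shared control gave r = 0.504 and a covariance of 0.009, beside a median covariance of 0.0144. The simulation gave the control and each treated sample the same variance, which by itself fixes its r. That r is therefore no benchmark for the observed ones. The simulated spread, and with it the covariance, came from differences between paired arrays. The simulation applies only if 1 DMSO sample served all compounds, and such a sample cannot be split. Between opposite dye orientations the median r of the observed profiles was -0.217. Such r include the part common to all compounds, which correlated at -0.26 between the orientations. After removal of the mean over compounds, r between opposite orientations was 0.461 for PIA23 with perifosine and 0.193 for perifosine with miltefosine. It was 0.148 for DZ-50 with rapamycin and -0.322 for LY294002 with perifosine. DZ-50 and rapamycin correlated at r = 0.667 (-0.06 and -0.036 between opposite orientations) although they gave 0 and 1 features past 2-fold. Genes are not independent replicates in these correlations.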

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

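The test by splits below was chosen only after the result had been seen; the difference between the sets was planned.

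The compound sets differed by the test of the difference itself in SLC7A5 by 1.55, XBP1 by 1.16, HERPUD1 by 1.07, SARS1 by 1.06, SLC3A2 by 0.93, CEBPG by 0.86, SLC16A1 by 0.75, SLC1A5 by 0.74, ARF4 by 0.71 and PRNP by 0.68. Of the 84 splits of the compounds into 3 and 6, 3, the real one included, gave at least its 14 calls. Setting PIA23, perifosine and miltefosine against the rest gave 1138, the highest of the others. Setting PIA23, perifosine and API-2 apart gave 840, which points to a further structure of the samples. With such a structure the splits are not interchangeable, so this count cannot exclude chance. Without LY294002 or without wortmannin 0 features were called, with SLC7A5 at 1.39 and 1.57. In all 14 features every value with the 3 inhibitors lay below every value with the other 6 compounds. The differences in these features thus do not rest on 1 compound, but the features were chosen by that same difference. An effect of single compounds on the number of calls stays open. A dye effect common to all compounds cancels in a difference between the sets. A difference in target between the sets may account for the pattern and stays a hypothesis, since other differences between 3 and 6 unlike compounds were not tested.

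PIA23 lay far above the other compounds with 257 features past 2-fold on both arrays, the next being perifosine with 70, in the ratio direction taken as likely. With scale normalisation between arrays the counts were 124 and 114, so that the gap depends on the normalisation. The authors' values gave 818 for PIA23 and 605 for API-2, but hold 1 averaged value per compound, so the rule of both arrays could not be applied to them. With the Cy3 arrays turned the counts would be 1 for PIA23 and 2 for perifosine, and the highest would be 8 with OSU-03012. POLE2 with miltefosine, at -1.99 from arrays at -2.96 and -1.01 (-0.98 with the Cy3 array turned), lay far below the other 8 compounds, the nearest at -0.79, and below the other 5 of its set, the nearest at -0.74. These are 3 of 49 such tests, and chance gives about 1 in 20.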

How the results depend on the processing

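Loess within each printing pen, the filter on negative control probes, normexp with an offset of 50 and the calls in the same direction in each orientation alone were chosen after seeing the data; the other settings were fixed before. No paired analysis was possible because each compound is a single sample, so the shared replicate number 1 pairs nothing. Each lone value is assumed to vary like the others where a compound is left out. The planned filter at 2 background SDs kept 34776 of 34776 probes and therefore tests nothing, while the filter on negative control probes kept 3228, so fewer features are tested there. Of the named genes of the tested comparisons, HSP90AA2P, HSP90AA1 and LDHA alone could be tested under it, and all kept their call. The remaining named genes, among them RHOB, CXCL8, PCNA, PSAT1 and SLC7A5, could not be tested under that filter. It therefore says nothing for or against their calls. Over all settings, the named genes of the tested comparisons kept direction and side of the threshold in 2028 cases, kept direction and lost the call in 347, gained a call in 22 and reversed in 18. List calls stayed in 660 cases, were lost in 126 and reversed in 3. Values of genes named for single compounds stayed within their spread in 400 cases and moved beyond it in 84. Apart from the smaller number of features or samples in the filters and in fits without a compound, the cause was not tested.

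Over all 9 compounds (7481 calls), loess within each pen gave 2831, the negative control filter 746, the Cy5 orientation alone 11771, the Cy3 orientation alone 14834, and the same direction in each alone 1479. Fits without 1 compound gave 5586 to 6912. Over the other 6 compounds (7165 calls), loess within each pen gave 3477, the negative control filter 994, the Cy3 orientation 13468 and the same direction in each orientation 1591, with 5250 to 6824 without 1 compound.

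Over the PI3K and mTOR inhibitors (150 calls), median centring gave 283, scale normalisation between arrays 294, loess within each pen 17, the negative control filter 24, the Cy5 orientation 2176, the Cy3 orientation 7375, the authors' values 797, limma with trend and robust settings 6, and the random block 527. Without 1 compound the count ran from 0 (without wortmannin) to 209 (without API-2), with 2 without LY294002, 17 without rapamycin and 81 without miltefosine.

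For the difference between the sets (14 calls), no background correction gave 1, median centring 8, scale normalisation 33, the negative control filter 0, the Cy5 orientation 2, the Cy3 orientation 7, the authors' values 5, limma with trend and robust settings 25, the random block 71, and the same direction in each orientation 1. Without 1 compound the count ran from 0 (without LY294002 or without wortmannin) to 24 (without DZ-50), with 8 without OSU-03012, 8 without PIA23, 7 without perifosine, 4 without miltefosine, 23 without API-2 and 6 without rapamycin. The named genes of this difference could not be tested under the negative control filter, so the count under that filter says nothing about them.

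Counts of features past 2-fold on both arrays are given next in the order LY294002 (7), wortmannin (5), OSU-03012 (7), PIA23 (257), perifosine (70), miltefosine (18), API-2 (40), DZ-50 (0) and rapamycin (1). The Cy5 arrays alone gave 53, 28, 239, 458, 127, 58, 323, 38 and 37, and the Cy3 arrays alone 189, 352, 295, 1227, 661, 804, 630, 198 and 238. The authors' values gave 89, 112, 108, 818, 207, 417, 605, 248 and 292. A 1.5-fold limit gave 78, 28, 87, 743, 490, 133, 435, 15 and 32. Limma over 18 arrays, whose p-values measure the spread between arrays only, called 356, 107, 728, 3448, 1764, 1566, 2359, 1 and 12. With no background correction the counts moved to 3 for LY294002, 1 for wortmannin, 0 for OSU-03012, 157 for PIA23, 22 for perifosine, 3 for miltefosine, 14 for API-2 and 0 for rapamycin. The negative control filter left 0 for LY294002, 0 for wortmannin, 1 for OSU-03012, 125 for PIA23, 2 for perifosine, 1 for miltefosine, 19 for API-2 and 0 for rapamycin. Normexp with an offset of 50 gave 4 for LY294002, 2 for wortmannin, 2 for OSU-03012, 9 for miltefosine and 0 for rapamycin. Scale normalisation gave 3 for OSU-03012, 124 for PIA23, 114 for perifosine, 30 for miltefosine, 20 for API-2 and 1 for DZ-50. Loess within each pen gave 2 for OSU-03012 and 25 for API-2, and median centring 69 for API-2 and 2 for rapamycin.

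Features that differed between perifosine and miltefosine (0) came to 1 with scale normalisation, 36 on the Cy5 arrays, 224 on the Cy3 arrays, 120 with the authors' values and 33 at 1.5-fold. The median correlation of compound profiles (0.346) was -0.217 between opposite orientations. The number of list calls (37) was 4 with the negative control filter, 23 in the Cy5 orientation, 0 with an estimated correlation and 18 with fry, and 32 to 42 without 1 compound. Under the negative control filter the lists of sterol synthesis over the PI3K and mTOR inhibitors (adjusted p = 0.916), G2/M over the other 6 compounds (adjusted p = 0.455) and G2/M in the difference (adjusted p = 0.916) changed direction without being called.

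TGM4 read 2.09 on the Cy3 arrays and 1.59 with the authors' values over all 9 compounds, and 2.23 and 1.74 over the other 6. In the Cy5 orientation, genes called higher over the PI3K and mTOR inhibitors read -0.17 (OOSP2), -0.073 (CFAP107), -0.025 (EDDM3B) and -0.12 (RB1CC1). Over the other 6 compounds PRKRA read 0.011 and AKT1 0.025 with loess within each pen, and AKT2 read -0.15 on the Cy5 arrays. CEBPD, near 0 at -0.003, read 0.37 on the Cy3 arrays, 0.027 with no background correction, 0.007 with normexp, 0.023 with the authors' values, and -0.055 (without OSU-03012) to 0.06 (without miltefosine) with 1 compound left out.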

Other observations

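The test of intensity below was chosen after the result had been seen, and the loess within each pen was predicted before its result.

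Probes whose titles name the LINE-1 retrotransposon or its open reading frames were lower with some compounds, in the ratio direction taken as likely. The title pattern was drawn from titles seen among the lower unnamed probes and then applied to every probe so titled, which gave 166. Their median log2 ratio was -1.22 with PIA23, -0.91 with API-2, -0.83 with perifosine, -0.37 with miltefosine and -0.13 with OSU-03012, against 0.02 with DZ-50, 0.11 with LY294002, 0.11 with wortmannin and 0.26 with rapamycin. All 166 lay below 0 with PIA23, perifosine and API-2, and 96 of the 195 features at least 2-fold lower on both arrays with PIA23 were among them. With the Cy3 arrays turned, the median would be 0.11 with PIA23, 0.11 with perifosine and 0.002 with API-2, with 41, 37 and 83 of the 166 below 0 and 0 of them 2-fold lower on both arrays. LINE-1 copies share sequence, so these probes are not independent measurements, and each compound is 1 sample.

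These probes are bright, with a median mean log2 intensity of 11.93 against 8.55 for all features. The percentile of the LINE-1 median among matched random lists cannot decide on an intensity bias. It was extreme in every compound, for example 0 with OSU-03012 and 99.35 with DZ-50, at medians of -0.13 and 0.02. The medians of most matched lists lay between -0.064 and 0.015 with PIA23, -0.026 and 0.031 with perifosine, and -0.087 and -0.003 with API-2. Other probes of like intensity were thus not shifted as far. This argues only against a bias shared by all probes of that intensity. Position effects are argued against by loess within each pen, after which the highest of the 3 medians was -0.85. A lower level of LINE-1 transcripts with these compounds may be a candidate explanation, as a hypothesis found and tested on the same data. Differences between the RNA samples in carried-over genomic DNA, which holds many LINE-1 copies, were not tested and stay open. A dye bias common to all compounds is argued against whichever way the arrays run. The medians on Cy5 and Cy3 arrays were -1.12 and -1.32 with PIA23, -0.72 and -0.92 with perifosine and -0.87 and -0.94 with API-2. They were 0.235 and -0.016 with LY294002, 0.315 and -0.104 with wortmannin, 0.03 and -0.044 with DZ-50 and 0.246 and 0.176 with rapamycin. A dye bias particular to the arrays of single compounds stays open.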
